A study of Mus musculus with 6 samples.

How the data were processed

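RNA was sequenced from 6 libraries of mouse mammary tumour explant cells, 3 carrying a control short hairpin RNA (shCTL) and 3 carrying a hairpin against CdGAP (shCdGAP). Per the labels' protocols, total RNA was extracted with TRIZOL, cleaned on RNeasy columns and made into libraries by standard Illumina procedures. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic 0.30, TopHat2 2.0.14, Cuffdiff 2.2.1 and DESeq were used, with genome build GRCm38. The deposited values were raw fragment counts per gene, 1 file per library. Per the file headers, these counts came from featureCounts 1.4.6 run on TopHat alignments with the Ensembl release 77 annotation. The options in the headers counted read pairs with both ends aligned, left out chimeric pairs and used strand setting 2 (reverse-stranded), so genes on opposite strands were counted apart. Each file held 41214 genes, and gene symbols from GENCODE M21 matched 40254 of them.

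Changes between groups were computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test compared shCdGAP with shCTL over all 6 libraries. Benjamini-Hochberg adjustment was made over the 13483 tested genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values given for single genes come from this edgeR test unless another tool is named. Log2 fold changes are shCdGAP over shCTL, and their standard errors (SE) were approximated as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM (the count as a share of the scaled library total, in parts per 1e+06), as mean ± SD with n = 3. A fold against a group at 0 counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts in a group the ratio of levels is given with its exact 95% binomial interval. Intervals and floors cover counting error only.

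Lists of genes were written before the data were examined, as were the main test, the alternatives marked as planned and the rule for named genes. There were 37 lists, covering epithelial and mesenchymal state, signalling, growth, stress, metabolism and markers of other cell types. Those with at least 5 tested members (36 lists) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, a form that called 0 lists in any fit. A list that fails this form is therefore not shown to owe its call to correlation among its genes. Fry was run beside camera. The fry p asks whether the genes of a list move on balance one way, and its mixed p asks whether they change in either direction. Neither fry p compares a list with other genes. No list median changed at the printed precision when genes at 0 counts in a group were set to their bound. The rule named Arhgap31, Cdh1 and Zeb2, the 12 largest rises and 12 largest falls among called genes with separate groups, a full symbol and at least 5 CPM in the higher group, the 5 smallest p-values in each direction, and up to 4 members of each list. The 4 were the 2 risen and 2 fallen members with the smallest adjusted p, or the 2 most abundant members where none passed. Some lists and named genes are not reported here. Erbb2, Vim, Zeb1, Snai2 and Xist, and the abundant genes of the closing section were chosen after their values were seen.

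Total counts ran from 19176540 to 26824249 per library, so 1 count was worth 0.0373 to 0.0521 CPM, and a count of 0 allows a level of up to 0.112 to 0.156 CPM (3 counts). The closest pair of libraries, shCTL replicates 2 and 3, had a chi-square per degree of freedom of 3.17 over genes, more than sampling noise gives, so each library was counted as a replicate. The replicate numbers were checked for pairing on deviations from the group means over the tested genes. Same-numbered libraries correlated at 0.36, 0.29 and 0.25 for numbers 1, 2 and 3, all above 0.1, so by the rule set before the fits were compared the numbers pair the libraries. The reported test does not use this pairing. Values with the replicate number as a block are given where they change the call of a named gene or a camera call of a list. Changes in fry calls, other genes and counts of called list members are given only in part. This rests on the data alone, since the labels name no shared day or batch, and crossed numbers 2 and 3 also correlated at 0.25 and 0.19.

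The edgeR steps were tested on simulated counts for the 13483 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The test called 19% of the 2-fold changes and 83% of the 4-fold changes, with 6.42% of its calls false. DESeq2 called 57% and 96%. A planted list was called by camera, and 0 of 36 random lists were. Random lists need not share the correlation found among related genes. In the data the estimated correlation of called lists ran from −0.016 (ErbB) to 0.84 (cholesterol synthesis), against the preset 0.01. The check therefore cannot tell how often lists of correlated genes are called falsely. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, a mean of at least 10 CPM, a required fold of at least 2, the replicate number as a block, and leaving out each library in turn. Leaving out both libraries numbered 1, and taking each fold change relative to the median of its 40 nearest expressed genes, were added after seeing the data. A pseudocount alternative planned for normalized values was not run, since the values were counts.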

Results

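Gene expression was compared between mouse mammary tumour explant cells that carried a control hairpin (shCTL, 3 libraries) or a hairpin against CdGAP (shCdGAP, 3 libraries). The cells derive from NMuMG, a line of normal mouse mammary gland epithelium, and express the receptor tyrosine kinase ErbB2. CdGAP is the product of Arhgap31 and switches off the small GTPases Cdc42 and Rac1. The series title asks how CdGAP bears on transcription of E-cadherin together with the repressor Zeb2. Fragments assigned to genes totalled 19176540, 26824249 and 25978281 in shCTL replicates 1 to 3 and 23151324, 22088774 and 25893195 in shCdGAP replicates 1 to 3. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

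Arhgap31, the targeted gene, was lower in all 3 shCdGAP libraries than in any shCTL library. Its levels were 13.2, 14.4 and 15.1 CPM in shCTL (14.3 ± 0.972, SD, n = 3) and 1.70, 9.16 and 8.21 CPM in shCdGAP (6.35 ± 4.06, n = 3). Cdh1, which encodes the epithelial adhesion protein E-cadherin, rose 3.31-fold in shCdGAP, from 232 ± 51.5 to 768 ± 85.3 CPM. Zeb2, a zinc finger repressor of Cdh1, fell 1.96-fold, from 34.4 ± 8.04 to 17.6 ± 1.75 CPM. Erbb2, the receptor gene that the cells express, fell from 692 ± 73.9 to 202 ± 56.8 CPM, and these counts do not separate an introduced copy from the mouse gene. Arhgap31 (ENSMUSG00000022799) lies on GRCm38 chromosome 16 from 38598340 to 38713274, Cdh1 (ENSMUSG00000000303) on chromosome 8 from 106603351 to 106670246, and Zeb2 (ENSMUSG00000026872) on chromosome 2 from 44983634 to 45117395. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the Arhgap31 log2 fold change was −1.16 ± 0.55 (SE) and did not pass (adjusted p = 0.19). Without shCdGAP replicate 1, the library with the lowest level, it was −0.71 and passed (adjusted p = 0.00407). The log2 fold change was 1.72 ± 0.194 for Cdh1 (adjusted p = 0.00193), −1.78 ± 0.232 for Erbb2 (adjusted p = 0.00341) and −0.97 ± 0.194 for Zeb2 (adjusted p = 0.0158). The Zeb2 log2 fold change without shCdGAP replicate 2 was −0.91 and no longer passed (adjusted p = 0.0668).

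**Figure D1:**
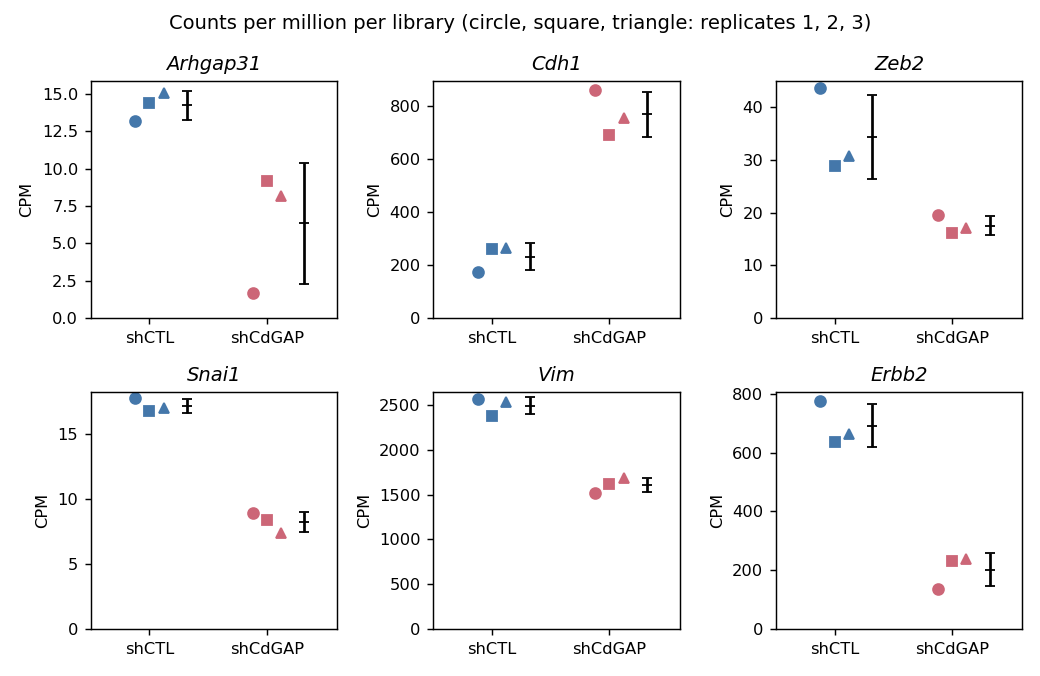
Level in CPM of Arhgap31, Cdh1, Zeb2, Snai1, Vim and Erbb2 in each library, with circles, squares and triangles for replicates 1, 2 and 3 and a black bar for the mean ± SD of each group (n = 3). All 3 shCdGAP libraries lie above the shCTL libraries for Cdh1 and below them for the other 5 genes, and Arhgap31 is lowest in shCdGAP replicate 1, at 1.70 CPM.

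The groups differed in many genes besides these. Of 13483 tested genes, 1396 rose and 1534 fell in shCdGAP, and 696 and 985 of these changed at least 2-fold. The largest rises took genes from near 0 to clear expression, among them Adgrl2, a latrophilin receptor (0.0841 ± 0.0416 to 55.1 ± 21.1 CPM), and Fam20c, a kinase of the secretory pathway (0.118 ± 0.0764 to 50.5 ± 11.4 CPM). They also took in Alpl, an alkaline phosphatase (0.182 ± 0.0687 to 56.6 ± 36.1 CPM), and Ehf, an epithelial ETS transcription factor (0.305 ± 0.203 to 70.0 ± 21 CPM). The largest falls included Gatm, an enzyme of creatine synthesis (133 ± 10.5 to 0.149 ± 0.117 CPM), the imprinted gene Peg3 (82.5 ± 30.8 to 0.103 ± 0.145 CPM) and Micu2, a regulator of mitochondrial calcium uptake (28.3 ± 4.02 to 0.0581 ± 0.0272 CPM). Acan, which encodes the proteoglycan aggrecan, was at 31.2 ± 6.91 CPM in shCTL with 1 count in shCdGAP (ratio 2210, interval 396 to 87200). Every called gene had non-overlapping groups, which a call on 3 and 3 libraries itself favours. Of all tested genes 44.1% had such groups. For a single gene chance gives 10%, but genes move together across the 6 libraries, so the 2 shares do not make a test. The first principal component (72.0% of the variance) parted the groups and the next (21.7%) parted shCdGAP replicate 1 from its replicates. The counts of risen and fallen genes depended on which libraries entered. They were 2753 and 3032 without shCdGAP replicate 1, 791 and 1054 without shCTL replicate 1, 538 and 856 without shCTL replicate 2, 563 and 892 without shCTL replicate 3, and 824 and 961 without shCdGAP replicate 2, and no gene called on all 6 libraries changed sign.

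**Figure D2:**
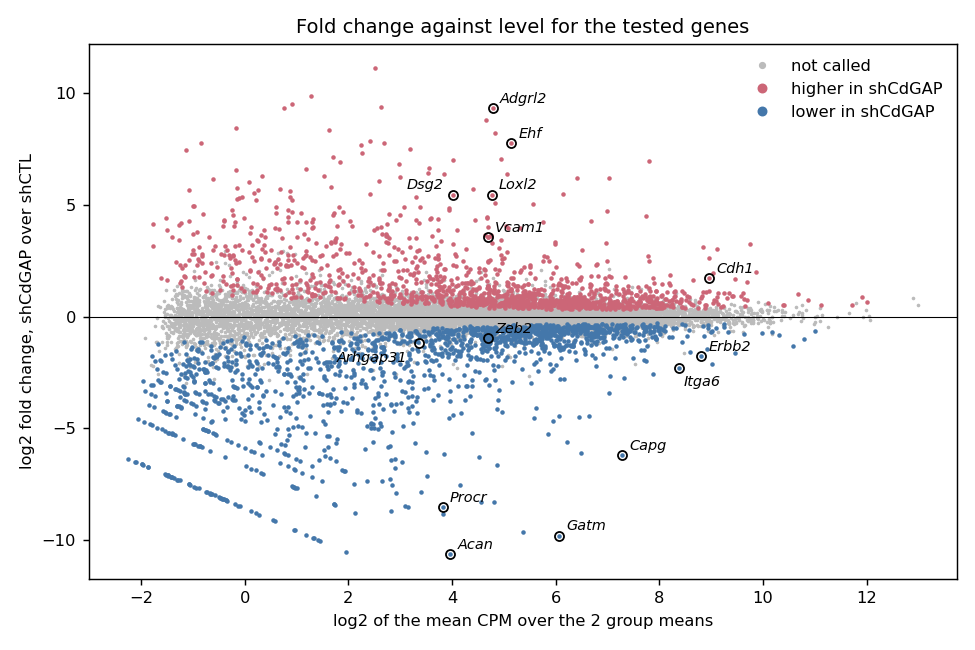
Log2 fold change (shCdGAP over shCTL) against log2 of the mean CPM over both groups for the 13483 tested genes, with called genes in red (1396 higher) and blue (1534 lower) and others in grey. Cdh1 lies among the abundant genes that rose, and Erbb2, Itga6 and Capg among those that fell.

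Many other genes at the extremes had few or no counts in a group. Zrsr1, an imprinted retrocopy of a splicing factor gene whose reads its parent gene could share, had 0 counts in shCTL and 781 in shCdGAP and was at least 263-fold higher. Lrfn3 had 1 count against 854 (ratio 864, interval 155 to 34200), and Prr16 had 1 against 424 (429, 76.6 to 17000). Slc17a4 (ratio 246, 83.7 to 1190), the kinase gene Dapk1 (221, 75.4 to 1080) and Gprc5c (157, 53.5 to 765) each had 3 counts in shCTL. The kinesin gene Kif12 rose from 0.0489 ± 0.0555 to 12.9 ± 3.24 CPM. Depp1 rose from 0.054 ± 0.0177 to 9.49 ± 13.1 CPM, with most of its counts in shCdGAP replicate 1, and its call was lost when any shCTL library was left out (adjusted p up to 0.0884). Erfe was at least 191-fold lower in shCdGAP, Tspan11 129-fold, the homeobox genes Nkx6-1 and Msx1 124-fold and 116-fold, and Majin 123-fold, each with 0 counts in shCdGAP and these folds as lower bounds. Slitrk5 (ratio 629, 112 to 24900), the granin gene Scg2 (513, 142 to 4240) and Irs1, an adaptor of the insulin receptor (422, 144 to 2050), had 1 to 3 counts in shCdGAP. The smallest p-values among risen genes belonged to Loxl2, a lysyl oxidase (1.22 ± 0.108 to 53.1 ± 0.682 CPM, log2 fold change 5.44 ± 0.142, adjusted p = 5.64e-05), and to the desmosomal cadherin gene Dsg2. They were followed by Adora1 (log2 fold change 6.43 ± 0.254), the deiodinase gene Dio3 (6.64 ± 0.258) and Poglut1, a glycosyltransferase of Notch (6.38 ± 0.249, adjusted p = 9.61e-05 for the last 3). Poglut1 lies on chromosome 16 from 38525137 to 38550258, close to Arhgap31, and rose from 0.328 ± 0.106 to 28.4 ± 2.01 CPM. Among fallen genes with the smallest p-values were Procr, the protein C receptor (log2 fold change −8.51 ± 0.23, adjusted p = 5.64e-05), Qrfp (−7.53 ± 0.223), Capg, an actin capping protein (−6.21 ± 0.202, 308 ± 31.6 to 4.16 ± 0.831 CPM), and Micu2 (−8.82 ± 0.3).

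Genes of epithelial adhesion and polarity mostly rose where they changed, while mesenchymal genes went both ways. Of 22 tested adhesion and polarity genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone). Besides Cdh1, these included Dsg2 (0.725 ± 0.104 to 31.8 ± 1.67 CPM) and the tight junction gene Cgn (35.5 ± 2.3 to 98.9 ± 11.9 CPM, adjusted p = 0.000797). The gene that fell was Epcam, an epithelial surface marker, with 92 counts in shCTL and 0 in shCdGAP (at least 30.3-fold lower). Camera called the list higher (adjusted p = 6.9e-05), and not with an estimated correlation (adjusted p = 0.47 with an estimated correlation). Of 13 keratins and epithelial regulators, 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.17). With at least 10 CPM required camera called that list higher (adjusted p = 0.032), though not with an estimated correlation (adjusted p = 0.58 with an estimated correlation). Ehf and the splicing regulator Esrp2 (31.8 ± 0.872 to 51.4 ± 3.19 CPM) rose. Krt20 (68.9 ± 3.66 to 33.4 ± 7.79 CPM) and Grhl2 (169 counts against 3, ratio 55.7, interval 18.7 to 273) fell. Among 19 mesenchymal genes, 6 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.79). Loxl2 and the fibronectin gene Fn1 (127 ± 30.5 to 463 ± 61.5 CPM) rose. Itga5 (104 ± 6.88 to 42.7 ± 5.45 CPM), Wnt5a (481 counts against 1, ratio 475, interval 84.9 to 18800) and the vimentin gene Vim (2500 ± 99 to 1610 ± 80.7 CPM, adjusted p = 0.00725) fell. Of 15 transcription factors of epithelial-mesenchymal transition (EMT), 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.85). Snai1 (17.2 ± 0.538 to 8.22 ± 0.774 CPM) and Hmga2 (576 ± 176 to 192 ± 50.6 CPM) fell with Zeb2. Twist2 (0.251 ± 0.0507 to 4.69 ± 2.3 CPM) and Foxq1 (6.92 ± 0.797 to 20.1 ± 8.99 CPM) rose. Zeb1 was at 32 ± 2.23 and 31 ± 0.935 CPM (adjusted p = 0.82). The Snai2 log2 fold change was −1.29 (adjusted p = 0.139), and it passed with the replicate block (−1.47, adjusted p = 0.0407) or without shCdGAP replicate 1 (−2.06, adjusted p = 0.00193). The Foxq1 call was lost when any shCTL library was left out (adjusted p up to 0.0884). With a library left out, 8 to 12 adhesion and polarity genes rose, 2 to 8 keratins and epithelial regulators rose, 3 to 6 mesenchymal genes rose and 4 to 8 fell, and 1 to 5 EMT factors rose and 2 to 5 fell.

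Genes of the ErbB pathway mostly fell where they changed, and so did targets of p53. Among 26 ErbB receptors, ligands and feedback genes, 12 fell and 3 rose (14 and 4 adjusted over the list alone), with Erbb2 among those that fell. The ligand gene Btc fell from 26.7 ± 4.82 to 3.84 ± 1.22 CPM and the feedback inhibitor gene Errfi1 from 341 ± 84.5 to 85.4 ± 10.9 CPM. The ligand gene Nrg1 (14.5 ± 1.85 to 37.3 ± 7.57 CPM) and the adaptor gene Grb7 (37.6 ± 2.75 to 99.2 ± 36.4 CPM) rose. Of 25 p53 targets, 9 fell and 0 rose, also when adjusted over the list alone, among them Mdm2, which encodes the ligase that degrades p53 (843 ± 217 to 191 ± 7.56 CPM), and Eda2r (97.1 ± 3.7 to 46.0 ± 4.64 CPM). Camera called both lists lower, at adjusted p = 0.013 for ErbB and 0.0017 for p53. Neither held with an estimated correlation (adjusted p = 0.47 with an estimated correlation for each). For ErbB the estimate of −0.016 lay below the preset 0.01. Its unadjusted camera p still went from 0.0029 to 0.029, so correlation among its genes is not what lost that call. The p53 estimate, 0.016, was also close to the preset. Of 22 immediate early genes, which growth signals switch on, 8 fell and 1 rose (8 and 2 adjusted over the list alone). Egr3 (1.91 ± 0.189 to 0.101 ± 0.0693 CPM) and Fosb (5.71 ± 2.37 to 0.519 ± 0.0374 CPM) fell and Klf6 (140 ± 12.2 to 202 ± 19.2 CPM) rose. That list missed the threshold (camera adjusted p = 0.058), and passed it without shCTL replicate 2 (0.017) or 3 (0.031) and with no filter on low counts (0.048). With an estimated correlation it passed in none of these 3 (adjusted p = 0.67, 0.69 and 0.61 with an estimated correlation). Of 26 apoptosis regulators, 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.46). Bmf (10 ± 2.97 to 195 ± 131 CPM) and Diablo (27.3 ± 1.94 to 39.9 ± 3.63 CPM) rose. Apaf1 (75.5 ± 5.14 to 39.2 ± 4.04 CPM) and Cflar (197 ± 39 to 102 ± 11.5 CPM) fell. Calls were lost for Grb7 without shCTL replicate 2 (adjusted p = 0.0561), for Klf6 without shCTL replicate 2 or 3 or shCdGAP replicate 2 (up to 0.113) and for Diablo when any library other than shCdGAP replicate 1 was left out (up to 0.111). The Diablo log2 fold change did not pass with no filter on low counts either (0.0564). With a library left out, 6 to 17 ErbB genes, 6 to 14 p53 targets and 4 to 10 immediate early genes fell, while 1 to 4, 0, and 0 to 2 of them rose. Immediate early genes with the replicate block numbered 3 risen and 7 fallen. Apoptosis regulators numbered 1 to 5 risen and 2 to 4 fallen with a library left out.

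Among inflammatory genes that changed, NF-kappaB targets mostly rose, while interferon genes fell where they changed and 18 of 29 were not called. Of 21 NF-kappaB targets and chemokines, 15 rose and 2 fell (17 and 3 adjusted over the list alone). The adhesion molecule gene Vcam1 rose from 4.09 ± 0.507 to 47.3 ± 6.33 CPM (adjusted p = 0.000163) and the chemokine gene Ccl7 from 3.44 ± 0.471 to 18.6 ± 2.75 CPM. The cytokine genes Lif (79.7 ± 6.87 to 44.5 ± 11.1 CPM) and Csf2 (1.87 ± 0.844 to 0.567 ± 0.217 CPM) fell. Of 29 interferon response genes, 11 fell and 0 rose (13 and 2 adjusted over the list alone), among them Oasl1 (43.7 ± 0.975 to 6.18 ± 0.73 CPM, adjusted p = 0.000163) and Oas3 (12.4 ± 2.4 to 0.0694 ± 0.0619 CPM). Camera called the first list higher (adjusted p = 1.7e-05) and the other lower (adjusted p = 0.0011), and neither held with an estimated correlation (adjusted p = 0.47 and 0.60 with an estimated correlation). In shCdGAP replicates 1 to 3 the list medians against the shCTL mean were 0.79, 1.7 and 1.7 for NF-kappaB and −0.27, −0.97 and −0.85 for interferon. Of 12 class I histocompatibility genes, which share reads within their family and are uncertain, 1 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.94). H2-Q4 (4.93 ± 0.619 to 9.76 ± 0.726 CPM) rose. The peptide transporter gene Tap1 (4.91 ± 0.521 to 0.465 ± 0.155 CPM) and H2-D1 (46.9 ± 2.03 to 19.2 ± 9.02 CPM) fell. With a mean of at least 10 CPM required, the interferon list was no longer called (adjusted p = 0.17). Calls were lost for Csf2 and H2-D1 when any library other than shCdGAP replicate 1 was left out (adjusted p up to 0.115 and 0.0951), for Lif when any library other than shCdGAP replicates 1 and 2 was left out (up to 0.0921) and for H2-Q4 without shCTL replicate 2 (0.0621). With a library left out, 9 to 16 NF-kappaB targets rose and 0 to 4 fell, 0 to 2 interferon genes rose and 6 to 19 fell, and 0 to 4 class I genes rose and 1 to 4 fell.

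Signalling pathways of development changed in part. Of 27 genes of the TGF-beta pathway, 8 rose and 2 fell (9 and 2 adjusted over the list alone), including the ligand gene Tgfb2 (1.52 ± 0.253 to 13.1 ± 1.92 CPM) and the receptor gene Tgfbr1 (105 ± 5.43 to 220 ± 7.12 CPM). Ltbp2 (0.962 ± 0.174 to 0.189 ± 0.107 CPM) and Tgfbr3 (6.17 ± 0.591 to 2.27 ± 1.12 CPM) fell. Camera called this list higher (adjusted p = 0.035), and not with an estimated correlation (adjusted p = 0.62 with an estimated correlation), without shCdGAP replicate 1 (0.20), without shCTL replicate 2 (0.061) or without both libraries numbered 1 (0.13). Its medians in shCdGAP replicates 1 to 3 were 0.56, 0.093 and 0.11. Of 9 Wnt targets, 5 fell and 0 rose, also when adjusted over the list alone, among them the receptor gene Lgr6 (55.3 ± 7.07 to 3.12 ± 0.813 CPM) and Axin2 (5.08 ± 1.19 to 1.49 ± 0.301 CPM). That list missed the threshold (camera adjusted p = 0.078), and passed it without shCTL replicate 3 (0.048) and with at least 10 CPM required (0.045). With an estimated correlation it passed in neither (adjusted p = 0.58 and 0.33 with an estimated correlation). Of 16 Notch pathway genes, 4 fell and 1 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.35). The receptor gene Notch4 (18.4 ± 0.904 to 1.5 ± 0.195 CPM) and the ligand gene Dll4 (6.02 ± 1.96 to 0.141 ± 0.0546 CPM) fell. Hey1 (0.769 ± 0.314 to 6.41 ± 4.19 CPM) rose. Of 18 YAP targets, 6 rose and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.50). Dlc1 (3 counts against 128, ratio 43.2, interval 14.4 to 212) and Wwc1 (185 ± 8.1 to 306 ± 42.9 CPM) rose. Ptpn14 (155 ± 6.65 to 82.2 ± 6.14 CPM) and Amotl1 (44.4 ± 4.17 to 29.9 ± 0.875 CPM) fell. Calls were lost for Tgfbr3 and Hey1 when any library other than shCdGAP replicate 1 was left out (adjusted p up to 0.119 and 0.0931), for Amotl1 when any shCTL library or shCdGAP replicate 2 was left out (up to 0.0739), for Wwc1 without shCTL replicate 1 or 2 (up to 0.0641) and for Ltbp2 without shCTL replicate 3 (0.0527). With a library left out, 5 to 9 TGF-beta genes rose and 0 to 5 fell, and 0 to 1 Wnt targets rose and 3 to 5 fell. Notch genes then numbered 0 to 4 risen and 3 to 7 fallen (2 and 5 with the replicate block), and YAP targets 1 to 9 risen and 1 to 5 fallen.

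Genes of the matrix and its receptors changed in both directions. Of 22 collagen and basement membrane genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.94). Col6a1 (36.8 ± 8.39 to 181 ± 41.4 CPM) and Nid2 (4.31 ± 0.513 to 12.9 ± 0.614 CPM) rose. The laminin gene Lamb1 (22.1 ± 3.68 to 3.14 ± 0.289 CPM) and Col5a1 (46.0 ± 4.88 to 13.4 ± 2.88 CPM) fell. Of 13 integrins, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.36). Itga6, a laminin receptor subunit and the most abundant of the 4 named, fell from 550 ± 102 to 112 ± 8.53 CPM and Itgb7 from 16.8 ± 0.614 to 1.80 ± 0.438 CPM. Itga1 (3.05 ± 0.453 to 48.5 ± 21.4 CPM) and Itgb6 (7.96 ± 3.55 to 31.4 ± 12.6 CPM) rose. Of 24 matrix proteases and inhibitors, 2 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.22). Adamts1 (0.685 ± 0.264 to 20.2 ± 7.81 CPM) and the urokinase gene Plau (0.416 ± 0.177 to 2.36 ± 0.412 CPM) rose. Adamts4 (19.8 ± 2.76 to 5.01 ± 1.51 CPM) and Adamts9 (1.90 ± 0.482 to 0.444 ± 0.119 CPM) fell. The Itgb6 call was lost when any library other than shCdGAP replicate 1 was left out (adjusted p up to 0.0875). Leaving out 1 library gave 4 to 8 risen and 5 to 7 fallen collagen and basement membrane genes, 1 to 2 and 2 to 6 integrins, and 2 to 3 and 3 to 10 proteases and inhibitors.

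Genes of cholesterol synthesis and the mitochondrial genome rose where they changed, while few genes of the ribosome were called. Of 24 cholesterol synthesis genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them Sqle (254 ± 5.68 to 484 ± 115 CPM) and Hmgcs1 (196 ± 37.1 to 601 ± 254 CPM), which encode enzymes of the pathway. Of these 24 genes, 0 rose without shCTL replicate 2 or 3 and 3 without shCTL replicate 1, while 13 rose and 2 fell without shCdGAP replicate 1. Of 13 mitochondrially encoded genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them mt-Nd5 (1080 ± 94.2 to 2190 ± 246 CPM) and mt-Nd2 (1400 ± 31.7 to 2320 ± 132 CPM). Mitochondrial genes took 1.68, 1.69 and 1.58% of counts in shCTL and 3.24, 2.51 and 2.32% in shCdGAP. Of 48 ribosomal protein genes, which share reads with pseudogenes and are uncertain, 4 rose and 0 fell (0 and 0 adjusted over the list alone), with Rps28 (223 ± 27.4 to 360 ± 54.5 CPM) and Rpl13 (337 ± 49.5 to 527 ± 75 CPM) the 2 with the smallest p. Over all 13483 tested genes 1396 rose, so 4 of 48 is no more than the share over all genes. No ribosomal gene rose without shCTL replicate 2 or 3 or relative to neighbouring genes, 1 rose without shCdGAP replicate 3, and 28 rose with both libraries numbered 1 left out. Mitochondrial genes that rose numbered 4 to 9 with a library left out. Camera called these lists higher, at adjusted p = 0.00092, 0.0011 and 0.0012, and none held with an estimated correlation (adjusted p = 0.69, 0.61 and 0.83 with an estimated correlation). The list medians in shCdGAP replicates 1 to 3 were 1.6, 0.46 and 0.38 for cholesterol, 0.88, 0.65 and 0.54 for mitochondrial and 0.40, 0.047 and 0.21 for ribosomal genes. Over all 36 tested lists camera called 9, of which 0 held with an estimated correlation, and fry called 19. The form with an estimated correlation called 0 lists in any fit, so it does not tell these 9 lists apart. Fry did not call the cholesterol list (adjusted p = 0.15, and 0.034 without shCdGAP replicate 1) or the ribosomal list (adjusted p = 0.26, and 0.043 with the replicate block). Calls were lost for Sqle and Hmgcs1 without shCTL replicate 2 or 3 (adjusted p up to 0.0596 and 0.0673), likewise for Rps28 (up to 0.0987), and for Rpl13 without these or shCdGAP replicate 3 (up to 0.13).

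Other metabolic lists were not called. Of 38 nuclear genes of oxidative phosphorylation, 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.94). Ndufv2 (75.9 ± 2.04 to 108 ± 5.29 CPM) and Sdha (187 ± 2.15 to 301 ± 44.4 CPM) rose. The ATP synthase genes Atp5j (143 ± 2.68 to 108 ± 2.37 CPM) and Atp5o (153 ± 4.87 to 120 ± 3.83 CPM, 12.7% of its exon bases shared with another gene) fell. Of 25 genes of glycolysis and hypoxia, 0 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.40), including the kinase genes Hk1 (325 ± 26.1 to 213 ± 29.1 CPM) and Pfkp (35.4 ± 14.1 to 9.40 ± 5.45 CPM). Of 27 genes of the unfolded protein response and amino acid stress, 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.54). Xbp1 (51.4 ± 8.68 to 84.9 ± 6.45 CPM) and Slc3a2 (261 ± 12.8 to 351 ± 26.7 CPM) rose. Sesn2 (98.6 ± 20.1 to 37.8 ± 7.93 CPM) and Shmt2 (302 ± 68.7 to 159 ± 42.8 CPM) fell. Of 13 housekeeping genes, Sdha rose and Gusb (71.4 ± 1.07 to 43.2 ± 3.64 CPM) fell, also when adjusted over the list alone (camera adjusted p = 0.72). Calls were lost for Atp5o, Hk1, Pfkp and Slc3a2 when any library other than shCdGAP replicate 1 was left out (adjusted p up to 0.162, 0.0812, 0.0948 and 0.143), for Atp5j and Shmt2 when any shCTL library or shCdGAP replicate 2 was left out (up to 0.109 and 0.147), for Ndufv2 when any shCTL library was left out (up to 0.0716), and for Xbp1 and Sdha without shCTL replicate 2 or 3 (up to 0.0837 and 0.063). The Atp5o log2 fold change and the Shmt2 log2 fold change did not pass with the replicate block either (adjusted p = 0.0682 and 0.0888). With no filter on low counts the Atp5j log2 fold change (adjusted p = 0.0543) and the Atp5o log2 fold change (0.0875) did not pass, nor did the Shmt2 log2 fold change with at least 10 CPM required (0.0539). With a library left out, 0 to 9 oxidative phosphorylation genes rose and 0 to 5 fell, and 0 to 1 genes of glycolysis and hypoxia rose and 0 to 8 fell. The replicate block gave 5 risen and 2 fallen oxidative phosphorylation genes, 3 and 4 of glycolysis and hypoxia, and 4 and 5 of the unfolded protein response and amino acid stress. Without 1 library, genes of the unfolded protein response and amino acid stress numbered 0 to 5 risen and 1 to 8 fallen, and housekeeping genes 0 to 4 risen and 1 to 4 fallen.

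Cell division genes set shCdGAP replicate 1 apart from the other libraries. Its median over 31 mitosis genes lay at −3.4 on the log2 scale against the shCTL mean, while replicates 2 and 3 lay at 0.57 and 0.59. The proliferation marker Mki67 was at 44.9 CPM in shCdGAP replicate 1 and at 722 and 672 CPM in replicates 2 and 3 (shCTL 363 ± 76.7). Over 35 genes of DNA replication and S phase the medians were −2.4, 0.12 and 0.27. Against replicates 2 and 3, replicate 1 was lower in 100% of the members of both lists, with a median of 16-fold for mitosis and 5.7-fold for S phase. Between the groups, 0 genes of either list rose or fell, also when adjusted over the list alone. Without shCdGAP replicate 1, 19 of the 31 mitosis genes rose and 0 fell, and 5 S phase genes rose and 4 fell. With both libraries numbered 1 left out, 23 mitosis genes rose and 1 fell, and 11 S phase genes rose and 8 fell. The group levels were 675 ± 157 and 605 ± 469 CPM for Top2a, 281 ± 57.4 and 261 ± 184 CPM for the ribonucleotide reductase gene Rrm1 and 206 ± 24.9 and 218 ± 117 CPM for Mcm7. Camera called neither list (adjusted p = 0.35 for mitosis and 0.12 for S phase), and with the replicate block the S phase list was called lower (adjusted p = 0.031), though not with an estimated correlation (adjusted p = 0.81 with an estimated correlation). Without shCdGAP replicate 1 the mitosis list was called higher (adjusted p = 8e-05), and without shCdGAP replicate 2 or 3 it was called lower (0.03 and 0.046), as was the S phase list (0.012 and 0.0055). None of these calls held with an estimated correlation (adjusted p = 0.65, 0.83, 0.83, 0.81 and 0.80 with an estimated correlation, in the same order).

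**Figure D3:**
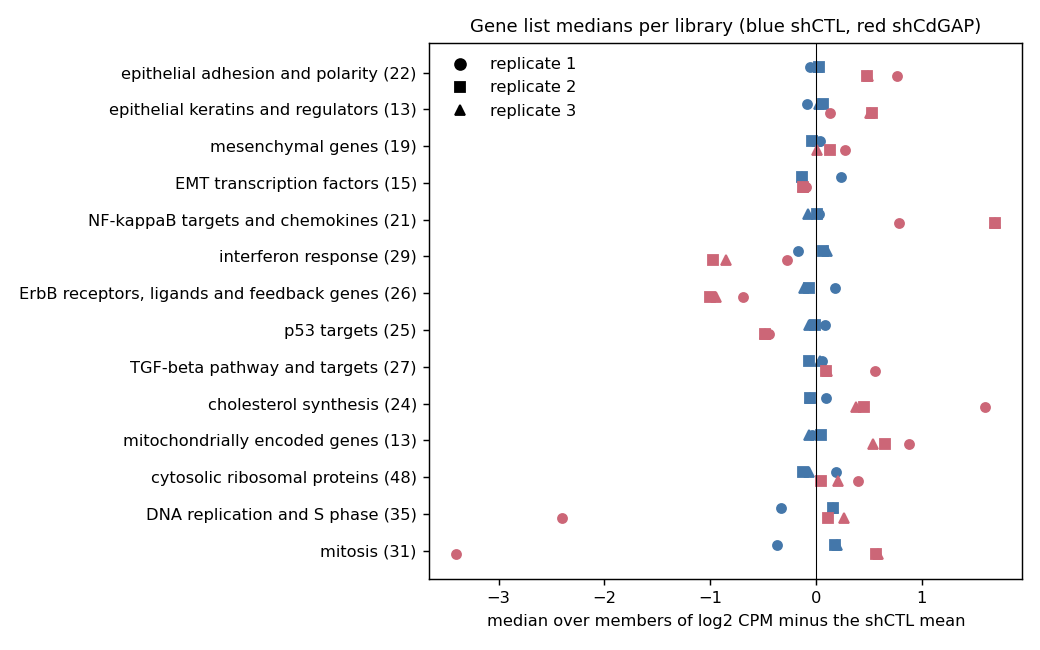
Median over the members of 14 gene lists of log2 CPM minus the shCTL mean, per library (blue shCTL, red shCdGAP; circles, squares and triangles for replicates 1, 2 and 3; number of tested members in parentheses). In shCdGAP replicate 1 the mitosis and S phase medians lie at −3.4 and −2.4, apart from all other libraries.

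Some markers of mammary and other tissue cell types changed, and camera called none of their lists while fry called all 6 tested. Fry, which does not compare a list with other genes, put the luminal (adjusted p = 0.00056), basal (0.00016), fibroblast (0.00016), endothelial (0.039) and immune (0.013) lists lower and the nerve and muscle list higher (0.0041). Its endothelial call was lost with the replicate block (0.17) and when any library other than shCdGAP replicate 1 was left out (up to 0.19), its immune call without shCTL replicate 2 or 3 (0.062 and 0.37) and its nerve and muscle call with no filter on low counts (0.80). Of 12 luminal markers, 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.24). The mucin gene Muc1 (8.05 ± 0.2 to 58.6 ± 18.7 CPM) rose. The casein gene Csn3 (24.4 ± 3.47 to 2.13 ± 0.454 CPM) and Foxa1 (32.2 ± 5.88 to 7.12 ± 1.14 CPM) fell. Of 8 basal and myoepithelial markers, 3 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.35). With at least 10 CPM required camera called the basal list lower (adjusted p = 0.045), though not with an estimated correlation (adjusted p = 0.33 with an estimated correlation). Nrg1 and Cnn1 (0.0637 ± 0.0809 to 3.16 ± 2 CPM) rose. Procr (28.1 ± 0.243 to 0.0713 ± 0.0231 CPM) and Itga6 fell. Of 6 fibroblast markers, 3 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.094), including Fbn1 (74 counts against 1, ratio 73.1, interval 12.7 to 2930) and Mfap5 (53 against 1, ratio 52.4, interval 9 to 2110). Of 6 endothelial markers, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.95). Ecscr (3.64 ± 1.38 to 22.8 ± 1.25 CPM) and Egfl7 (3.55 ± 0.282 to 7.56 ± 1.98 CPM, 9.41% of its exon bases shared) rose. Tek (31 counts against 0, at least 10.2-fold) fell. Of 9 immune cell markers, 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.32). Itgam (0.213 ± 0.123 to 1.41 ± 0.236 CPM) rose. S100a8 (37.5 ± 10.9 to 3.26 ± 2.61 CPM) and Mrc1 (105 ± 28.3 to 23.7 ± 14.3 CPM) fell. Of 4 adipocyte markers, too few for a list test, Fabp4 (1.99 ± 0.599 to 0.377 ± 0.234 CPM) and Cidec (2.54 ± 0.511 to 0.814 ± 0.425 CPM) fell, also when adjusted over the list alone. Of 5 nerve and muscle markers, Mbp rose (22 ± 2.46 to 44.2 ± 4.4 CPM; 3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.17). Median and mean differed in sign for the mesenchymal, EMT factor, class I and oxidative phosphorylation lists, and the camera direction differed from the median for mitosis, endothelial and oxidative phosphorylation genes, none of which was called. Calls were lost for Cidec when any library other than shCdGAP replicate 1 was left out (adjusted p up to 0.144), for Mrc1 when any shCTL library or shCdGAP replicate 2 was left out (up to 0.0803), for Fabp4 without shCTL replicate 1 or 3 or shCdGAP replicate 2 (up to 0.0709) and for Egfl7 without shCTL replicate 2 or 3 (up to 0.0936), and with the replicate block for Tek (0.0547) and Cidec (0.0778). Leaving out 1 library gave 1 to 3 risen and 4 to 5 fallen luminal markers, 2 to 3 and 3 to 5 basal, 0 and 3 to 4 fibroblast, and 1 to 3 and 0 to 3 endothelial. It gave 1 to 2 risen and 1 to 5 fallen immune cell markers, 0 and 0 to 4 adipocyte, and 1 to 2 and 0 to 1 nerve and muscle markers.

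Median log2 fold changes differed between chromosomes and between parts of the same chromosome. Over 9305 genes with at least 10 CPM, the median log2 fold change was 0.41 on chromosome 17, where 85.8% of genes lay above 0, and 0.33 on chromosome 13, 0.29 on chromosome 19 and 0.27 on chromosome 8. It was −0.30 on chromosome 16, which holds Arhgap31, with 22.4% of genes above 0, and −0.22 on chromosome 10. In windows of 40 neighbouring genes, chromosome 10 lay between −0.13 and 0.15 up to the window that starts at 62.9 Mb and reached −0.56 beyond it. On chromosome 6, with a median of 0.045, the first 9 windows lay at 0.24 to 0.47 and the other 29 at −0.25 to 0.15. On chromosome 17, 139 of these genes rose and 14 fell. The 40 expressed genes nearest to Arhgap31 had a median of −0.26, those nearest to Cdh1 0.14, those nearest to Zeb2 −0.14, those nearest to Erbb2 −0.23, those nearest to Poglut1 −0.28 and those nearest to Epcam 0.47. Relative to such neighbours 125 of 137 named genes kept their call and 12 lost it, which were Atp5j, Atp5o, Csf2, Foxq1, H2-Q4, Klf6, Ndufv2, Rpl13, Rps28, Sdha, Shmt2 and Slc3a2. Xist, the noncoding RNA of the inactive X chromosome, rose from 372 ± 42.3 to 1490 ± 342 CPM (adjusted p = 0.00133), and genes on chromosome X had a median of 0.053.

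**Figure D4:**
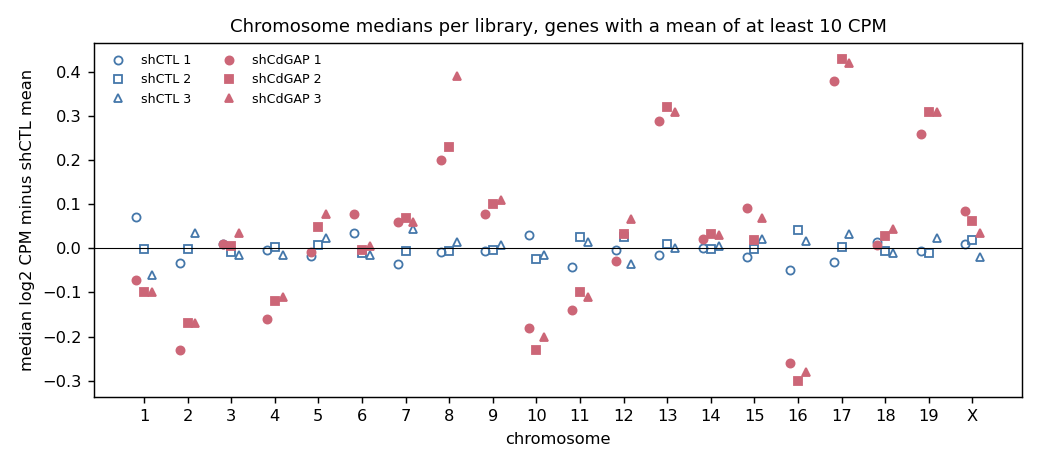
Median log2 CPM minus the shCTL mean over the genes of each chromosome (at least 10 CPM), per library (blue shCTL, red shCdGAP; circles, squares and triangles for replicates 1, 2 and 3). Each shCTL library is set against the mean of the other shCTL libraries, without itself. The 3 shCdGAP libraries lie together at 0.38, 0.43 and 0.42 on chromosome 17 and at −0.26, −0.30 and −0.28 on chromosome 16, apart from the shCTL libraries.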

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

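Leaving out both libraries numbered 1 and taking changes relative to neighbouring genes were chosen after the results were seen. Cdh1 stayed higher and past the threshold under every alternative run, with log2 fold changes of 1.54 to 1.82 when a library was left out. Counts of genes higher and lower in shCdGAP were 1396 and 1534 as reported. They were 870 and 825 with a mean of at least 10 CPM, where fewer genes were tested, 696 and 985 with a fold of at least 2, and 3475 and 3640 with both libraries numbered 1 left out. Leaving out 1 library gave 538 to 2753 higher and 856 to 3032 lower genes, and 38.6% of calls were higher without shCTL replicate 2 against 47.6% as reported. The DESeq2 Wald test gave 1894 and 1949, its size factors in edgeR 1419 and 1546, no filter 1316 and 1636, and changes relative to neighbouring genes 1076 and 1435, with 16 of the reported calls changing sign in the last and 0 in the others. The Arhgap31 log2 fold change was −1.51 to −0.706 with a library left out and −0.759 (adjusted p = 0.000408) with both libraries numbered 1 left out. It passed only in this fit and without shCdGAP replicate 1 (adjusted p = 0.00407), where the spread within shCdGAP is smaller, and DESeq2 gave an adjusted p of 0.114. The Zeb2 log2 fold change was −1.08 to −0.777 with a library left out, past the threshold in all but the fit without shCdGAP replicate 2, and the cause was not tested. Camera called 9 to 11 lists with a library left out, 0 with an estimated correlation in any fit, and fry called 19 as reported and 14 to 26 with a library left out. The mitosis list (gene list: mitosis), not called as reported, with a median of 0.039 and a camera direction of down, had adjusted p-values of 8e-05 to 0.45 with a library left out and was called higher without shCdGAP replicate 1 (8e-05) and with both libraries numbered 1 left out (3.2e-05), and in neither with an estimated correlation (adjusted p = 0.65 and 0.52 with an estimated correlation). The first of these fits lacks only shCdGAP replicate 1, the library with low cell division genes. The Rrm1 log2 fold change, −0.102 as reported, turned to 0.24 (adjusted p = 0.012) with both left out and was 0.402 (adjusted p = 0.0745) without shCdGAP replicate 1 alone. Rrm1 was at 48.8 CPM in that library against 363 and 373 CPM in shCdGAP replicates 2 and 3, so leaving it out turned the sign. The cause of its low level there was not tested. With both left out the keratin list was also called (adjusted p = 0.039), though not with an estimated correlation (adjusted p = 0.57 with an estimated correlation). Of 139 named genes called, 105 kept their call in every fit with a library left out that tested them (Tek was tested in 3 of 6). The call was lost at least once for 34, and 0 changed sign. Many named genes were chosen for small p-values or large changes, so they stand for the most stable calls. Of all reported calls, 46.9% were kept without shCTL replicate 2, the fit that kept fewest, and 99.8% without shCdGAP replicate 1, the fit that kept most. The replicate block gave 1277 and 1468 genes and an Arhgap31 log2 fold change of −1.41 (adjusted p = 0.125), with 4 of 137 named calls lost (Atp5o, Cidec, Shmt2 and Tek). Beside these, Snai2 and the S phase list, it changed no other call of a named gene or by camera. The replicate block kept 83.2% of all reported calls. It also moved counts of list members, with 9 interferon genes fallen against 11 as reported, 9 matrix proteases and inhibitors fallen against 7, and 10 cholesterol genes risen against 8. By fry it called 17 lists, with the ribosomal (0.043) and keratin lists (0.031) gained and the TGF-beta (0.073), endothelial (0.17) and mitochondrial lists (0.09) lost among the changes. In the simulation, where few genes were changed, the test called 19% of 2-fold changes. In the data 21.7% of tested genes were called, which eases the adjusted threshold, so that share cannot be carried over. Of the 1396 higher and 1534 lower genes, 696 and 985 changed at least 2-fold, so smaller changes were also called. Small changes of single genes could still be missed.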

Other observations

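The single-allele test, the check of GC content and gene length and the count of calls kept relative to neighbouring genes were chosen after the results were seen, as were the genes named here. Called genes that changed at least 8-fold numbered 193 higher and 405 lower, and the 8 most abundant of each are given here. The neutrophil chemokine gene Cxcl5 rose from 165 ± 26.8 to 1560 ± 1190 CPM and Igfbp7 from 121 ± 17.3 to 985 ± 421 CPM. The ceruloplasmin gene (Cp) rose from 96.6 ± 35.1 to 824 ± 347 and the gene for lipopolysaccharide binding protein (Lbp) from 3.52 ± 1.04 to 444 ± 37.7 CPM. The gene for vitamin D binding protein (Gc) rose from 17.9 ± 10.6 to 411 ± 92.2 and complement C3 from 3.46 ± 2.42 to 256 ± 89.9 CPM. The cadherin gene Cdh16 (9.45 ± 0.659 to 246 ± 55.2 CPM) and the zinc transporter gene Slc39a4 (23.5 ± 3.48 to 228 ± 53.2 CPM) completed the 8 highest. Of the 8 most abundant in shCTL, Capg and Gatm are given above. Prkg2 fell from 237 ± 50.4 to 22.2 ± 5.12, the heparan sulfatase gene Sulf2 from 190 ± 14.4 to 8.61 ± 3.98 and Arap3 from 177 ± 20.5 to 2.63 ± 1.41 CPM. S100a7a fell from 168 ± 6.13 to 7.42 ± 1.58, Ptprn from 146 ± 29.2 to 3.00 ± 1.31 and the P-selectin gene Selp from 128 ± 1.66 to 5.91 ± 1.93 CPM. The adjusted p of these 16 genes in the edgeR test was at most 0.013.

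Some genes were at or near 0 in a group and expressed in the other. With a mean of 5 CPM or more in a group and below 0.25 CPM in the other there were 77 genes, 54 of them off in shCdGAP and 23 off in shCTL. By the same limits, shCdGAP replicate 1 differed from its replicates in 2 genes and each of the other 5 libraries from its replicates in 0. The imprinted genes Peg3, Zrsr1 and Dio3 are among the named genes at or near 0 in a group.

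Neighbouring genes shifted together, with an absolute median over 0.3 in 123 of 861 windows of 40 genes against at most 3 in 1000 shuffles of gene order, which any regional cause would give. A smooth fit on GC content and exon length left chromosome 17 at a median of 0.37, which argues against those biases as the whole cause. Relative to neighbouring genes 76.1% of the calls were made again. That outcome was likely from the start, since window medians reached at most 0.59 while 696 higher and 985 lower genes changed at least 2-fold. It shows that shifts of this size over 40 genes do not account for most calls. Shifts of fewer genes are not removed this way and were not tested. A difference in DNA copy number between the cells that received each hairpin was tested by that count of windows alone and cannot be told apart from other regional causes, and DNA was not analysed here. A response to the knockdown that spreads along chromosomes was not tested and moves with the same groups.

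For the genes expressed in a single group, lower depth in the group at 0 would put nearly all of them on the same side, and 0.701 of them were off in shCdGAP. Total counts ran from 19176540 to 26824249 per library in shCTL and from 22088774 to 25893195 in shCdGAP. At such similar depths a gene at 5 CPM would not fall below 0.25 CPM. These values argue against lower depth for the 77 genes. Fewer genes were detected in shCdGAP (17400 ± 81.9 against 18700 ± 245), a count that does not separate depth from genes that are off there. Fibroblasts or leukocytes in shCTL with a usual content of abundant transcripts are argued against by all 4 such markers tested, each below 1 CPM in shCTL or higher in shCdGAP, with Col1a1 at 1.63 against 2.67 CPM, Col3a1 at 0 against 0.0559, Lyz2 at 0.445 against 0.19 and Ptprc at 0.20 against 0.216. Other markers fell, with Mrc1 at 105 against 23.7 CPM, S100a8 at 37.5 against 3.26 CPM and 3 of 6 fibroblast markers lower and 0 higher (fry adjusted p = 0.00016). These come from 6 of 22 listed fibroblast markers and 9 of 25 immune markers, of which 1 immune marker rose and 2 fell. The rest were too low to test, among them Lum, Thy1, Dpt, Adgre1, C1qa and Tyrobp at 0 CPM in every library. Cells without these transcripts and the 4 above are not excluded. Loss or gain of a single active allele cannot be told apart from other causes, because the 3 imprinted genes named above prompted the test and were left out of it (3 of 20 with them). Of the 17 other imprinted genes with at least 5 CPM in a group, 0 were expressed in a single group where 0.12 were expected (Fisher exact p = 1, two-sided), too few to decide. Of 333 X-linked genes with at least 5 CPM in a group, 5 were expressed in a single group, at 1.5% against 0.69% of autosomal genes (odds ratio 2.19, Fisher exact p = 0.09). A candidate explanation is that the groups were grown from different cells of the explant, and a response to the knockdown itself, which the design names, stays open beside it, since the labels do not tell hairpins or clones apart within a group.

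Whether the position of shCdGAP replicate 1 is a stronger form of the response seen in replicates 2 and 3 could not be decided. Across 13483 genes, which are not independent replicates, the difference of replicate 1 from replicate 2 had a Pearson r of −0.18 with the change in replicate 3 against shCTL, and −0.076 with the replicates exchanged, where a stronger response alone would give a positive value. Replicates 2 and 3 lay together on the second principal component (−31.4 and −43.2 against 66.6 for replicate 1). What they share lowers both r values whatever the strength of the response. On the first component, which parted the groups, replicate 1 lay farthest from shCTL (75 against 61.4 and 57.2). Control cells mixed into replicates 2 and 3 would lend them the genes that replicate 1 lacks, but the 2 such genes kept a median share of 0.0038 of their shCTL level there, and the 17 genes with at most 3 counts in replicate 1 kept at most 0.039, against 0.61 for Arhgap31. In that library 489 genes differed over 4-fold from the mean of the other 2 of its group, against 59 and 98 for replicates 2 and 3, with cell division genes low, cholesterol genes high and mitochondrial genes at 3.24% of counts. A difference in growth state at harvest could give such values and was not tested, and shCTL replicate 1, with a mitosis median of −0.37, lay on the same side of its own group.

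Dividing the 6 libraries into 3 and 3 allows 10 splits, too few for a share under 0.05. The real split called 2930 genes and the highest of the others 0 in the edgeR test, also among the splits that part all 3 same-numbered pairs. Every other split put libraries of both kinds in each group, so the difference between them widened the spread within groups and left little to call. The contrast of 2930 with 0 therefore adds no evidence beyond the test itself.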
